A study of Danio rerio with 6 samples.

How the data were processed

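RNA of whole zebrafish embryos was measured by sequencing after treatment with SB505124, a small-molecule inhibitor of the type I receptors ALK4, ALK5 and ALK7 that carry Nodal, activin and TGF-beta signals. Per the labels, treatment began either at sphere stage or at 30% epiboly, and embryos were frozen at shield, tailbud or 7-somite stage, which gives 6 groups from 2 onsets and 3 harvest stages. Each sample held 30 to 60 embryos. Per the labels' protocols, RNA was isolated with the Qiagen RNeasy Mini kit and libraries were made with the Illumina TruSeq RNA v2 kit. No untreated group was analysed here, so each onset comparison sets the earlier treatment against the later one.

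Per the file headers, the authors deposited upper-quartile normalized (UQN) means per group, which are whole-number scores on a normalized scale and not raw counts. A standard error stands beside each mean, as a score on the same scale, per the file headers. The deposited table also gives a ratio for each stage and a yes or no call of differential expression at a 50% change. Within rounding, the ratio equals the epiboly-treated mean plus 1 over the sphere-treated mean plus 1 for 13321 of 13321 records. DESeq 1.6.1 is named in the submitters' processing notes with no role. The aligner, the counting tool and the genome build are not given in the sources used here, so no coordinates are printed. The authors' table lists 13321 RefSeq transcript records, and the highest group mean of each record is at least 100, so transcripts that stayed low in every group are missing from every count below.

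The values behind each mean were not analysed here. Of 11992 standard errors between 0 and 5, 11992 lie on the grid that 3 whole-number values can give, within the rounding of the deposited errors, against 10.4% expected by chance, so each mean was taken to rest on 3 values. This number was inferred from the table, while the labels list 1 sample per group. No source used here says whether the 3 values came from separate clutches, so p-values measure only the spread between them, which may be technical. Sequencing depth is unknown, as no whole reads could be recovered from rounded means. The group means sum to between 15311014 and 21048013. The median relative standard error of records at 100 or more runs from 2.46% in epiboly-treated shield embryos to 5.18% in sphere-treated shield embryos.

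Records were given gene symbols from a RefSeq gene table of assembly GRCz12tu (GCF_049306965.1), used for names only. Of the records, 12182 matched by gene identifier and 42 by accession, and 1097 did not match and were kept under their accession. Where a symbol had several records the one with the highest mean was kept, which set 47 aside and left 13274 genes. Paralogs with near-identical sequence, such as the hatching enzyme genes he1.1 and he1.2 or the cathepsin genes ctslb and ctslb.4, may share reads, and their separate values are uncertain.

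Log2 ratios are log2 of (sphere-treated mean + 5) over (epiboly-treated mean + 5), a scale that understates changes of low genes. The plan written before the data were examined assumed 1 value per group. It counted a gene at a stage when the ratio was at least 2-fold and the higher mean at least 50, and tested onset with limma 3.58.1 on the 6 group means, with harvest stage as a block and 2 residual degrees of freedom. The same limma fit, with onset as the block, tested the steps from shield to tailbud and from tailbud to 7-somite. A minimum mean of 10 removed 0 genes. Because the table holds standard errors, a test per stage was added after the data were seen. It takes the variance of log2(mean + 5) from the deposited standard errors of both groups by the delta method, moderates it across genes with limma's squeezeVar (4 degrees of freedom per gene before moderation), and compares the ratio with its standard error. Differences of the onset effect between 2 stages were tested in the same way. All p-values are two-sided and adjusted by Benjamini-Hochberg over the 13274 genes, with a threshold of 0.05, and "rose", "fell", "higher" and "lower" as calls refer to this limma-moderated test unless a size rule is named.

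Simulated data gave every gene, in both groups of a stage, the same extra spread (dispersion), a median derived from the deposited standard errors. The test at shield then recovered 98% of 2-fold and 64% of 1.5-fold changes. Recovery was 98% and 74% at tailbud, and 98% and 90% at 7-somite. False calls made up 1.1%, 5.1% and 7.6% of the simulated calls. Real genes and groups differ in spread, so these rates need not hold for the real table. The stage-blocked test recovered 100% of simulated 2-fold changes and 60% of 1.5-fold changes. These were drawn as equal at the 3 stages, with the same spread for every gene. In the real groups it called none of the 7 genes lower and 1 higher by at least 2-fold at all 3 stages. A count of 0 by this test therefore leaves shared changes possible.

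Before the data were examined, 27 gene lists were fixed: Nodal signalling, endoderm, prechordal plate and hatching gland, notochord, floor plate and Hedgehog response, paraxial mesoderm and somite, skeletal muscle, heart and lateral plate, blood and endothelium, pronephros, forebrain and eye field, midbrain and hindbrain, posterior body and tailbud, neurogenesis, neural crest, epidermis and periderm, planar cell polarity and neural tube morphogenesis, extracellular matrix, BMP and dorsal organizer, FGF response, Wnt response, retinoic acid, yolk syncytial layer, germ cell and maternal, p53 and stress, cell cycle, and ribosomal proteins. The median ratio of a list is given with its percentile among 10000 random lists of the same size, matched on mean level in 20 bins. Percentiles describe these groups and are not p-values. Some genes stand in more than 1 list.

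Genes were named by a rule fixed in advance: at each stage the 5 most higher and 5 most lower genes among those at least 2-fold changed with the higher mean at least 50, then up to 5 higher and 5 lower genes at least 2-fold changed in the same direction at all 3 stages, up to 4 members per list with the largest mean change over the stages among members with a mean of at least 50, and the 5 most higher and 5 most lower genes of each developmental step past the limma test. Clone and predicted-gene names were counted and not named. Other genes are named only where the text says that they were chosen after their values were seen.

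Alternatives were pseudocounts of 1 and 20, fold thresholds of 1.5 and 3, minimum levels of 20 and 200, rescaling of the groups by TMM factors or to equal totals, centring on the median gene, limma without a trend or a block, and leaving out a stage or a group. Replicates could not be left out in turn from means and standard errors. Values written with ± are the authors' means and their standard errors. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.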

Results

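Whole zebrafish embryos were treated with the Nodal receptor inhibitor SB505124 from sphere stage or from 30% epiboly and harvested at shield, tailbud or 7-somite stage. The study set out to find transcripts connected with closure of the neural tube, which depends on when Nodal signalling is blocked. For each of the 6 groups the authors' table gives a normalized mean and its standard error, and the labels list 1 sample of 30 to 60 embryos per group. Each mean was taken to rest on 3 values, a number inferred from the standard errors, and what separates these values is unknown. Embryos treated from sphere stage are called sphere-treated below, and those treated from 30% epiboly are called epiboly-treated. The means of all records sum to 20554558 in epiboly-treated and 21048013 in sphere-treated embryos at shield. They sum to 16816560 and 16933934 at tailbud, and to 15988680 and 15311014 at 7-somite.

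The first comparison asked how the earlier start of inhibition altered transcripts at shield stage, when the dorsal organizer forms. Genes of the Nodal pathway itself, taken first, were lower or near equal in sphere-treated embryos. Of the 12 measured members 5 fell and 0 rose, with the same 5 and 0 adjusted over the list alone. The type I receptor gene acvr1ba fell from 6045 ± 195 to 3278 ± 427 (log2 ratio -0.88, limma adjusted p = 0.0083). The gene of Vg1, a partner of Nodal ligands, is gdf3, and it fell from 1437 ± 46.9 to 731 ± 132 (log2 ratio -0.97, limma adjusted p = 0.012). Over both onsets, acvr1ba and gdf3 also fell from shield to tailbud (log2 change -1.41 and -2.635), so a difference in developmental time could lower them too. The Nodal ligand genes ndr1 and ndr2 and the antagonist genes lft1 and lft2 were not analysed here.

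Mesendoderm genes were lower in sphere-treated embryos at shield. In the endoderm list 8 of 11 members fell (9 adjusted over the list alone) and 0 rose, and the list median was -0.93. sox17, a marker of endoderm, fell from 80 ± 13.9 to 9 ± 4.33 (log2 ratio -2.60, limma adjusted p = 0.0074). The Nodal target gene mixl1 fell from 780 ± 28.9 to 262 ± 89.8. In the notochord list 7 of 9 members fell (7 adjusted over the list alone), among them noto, which is required for notochord formation (log2 ratio -1.09). The organizer genes gsc (141 ± 7.8 to 24 ± 11.9) and lhx1a (181 ± 2.33 to 44 ± 27.7) fell. In all, 5 of the 10 genes of the prechordal plate and hatching gland list fell (5 adjusted over the list alone), with a list median of -0.16 at percentile 11.7. Of 18 paraxial mesoderm genes 8 fell and 1 rose (10 and 2 adjusted over the list alone), with ripply1 down from 64 ± 9.02 to 12 ± 3.21. The largest fall among named genes was that of tbx1, a gene of pharyngeal and cardiac mesoderm, from 66 ± 6.89 to 6 ± 4.37 (log2 ratio -2.69, limma adjusted p = 0.0083). The yolk syncytial layer regulator mxtx2 fell from 222 ± 30.8 to 35 ± 19.8, but of the 13 genes of that layer's list 6 rose and 3 fell (7 and 3 adjusted over the list alone), with a median of 0.47. Responses to FGF, which acts with Nodal at the margin, were also lower. Of 14 genes 11 fell and 2 rose, with the same counts adjusted over the list alone. The feedback inhibitor gene dusp6 fell from 5206 ± 171 to 3340 ± 260.

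Genes of the forebrain and epidermis lists were among those higher at shield. fezf2, a forebrain gene, was at 2 ± 0.667 in epiboly-treated and 90 ± 42.6 in sphere-treated embryos (log2 ratio 3.76, limma adjusted p = 0.0071). dlx3b, of the preplacodal and epidermal ectoderm, rose from 93 ± 24 to 1214 ± 405 (log2 ratio 3.64). The protocadherin gene pcdh19 rose from 72 ± 19.2 to 917 ± 311. mdkb (57 ± 6.49 to 418 ± 138) and a2m2d (121 ± 13.4 to 940 ± 309) were the other genes of the 5 that rose most, after 1 record without a symbol had been passed over. In the epidermis and periderm list 15 of 25 genes rose and 2 fell (the same 15 and 2 adjusted over the list alone), with tp63, the regulator of basal epidermis, up from 121 ± 19.7 to 706 ± 151. Of 15 forebrain genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), and otx1 went from 375 ± 41.5 to 2084 ± 604. Of 13 posterior genes 6 rose and 1 fell (6 and 2 adjusted over the list alone). The caudal-type gene cdx1a went from 263 ± 42.3 to 1627 ± 479. Of 15 Wnt response genes 9 rose and 2 fell (9 and 3 adjusted over the list alone). Both fzd8b and the Wnt antagonist gene dkk1b fell by 1.87 and 2.09 on the log2 scale. Of 19 genes of BMP signalling and the dorsal organizer 11 rose and 5 fell (12 and 5 adjusted over the list alone). For example, szl, a BMP feedback inhibitor, rose from 1172 ± 183 to 3656 ± 194, and the dorsal antagonist nog1 fell from 240 ± 19.1 to 46 ± 21.4.

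At the same stage, the 18 measured germ cell and maternal genes all fell (18 adjusted over the list alone), with a list median of -0.56. The maternal RNA-binding protein gene cth1 fell from 487 ± 29.7 to 153 ± 48.1, and nanog, a regulator of zygotic genome activation, from 5269 ± 449 to 1619 ± 506. Across the 13274 genes, which are not independent replicates, the shield ratio and the change from shield to tailbud correlated at Pearson's r = 0.58. By sign alone, without a test, the change from shield to tailbud was above 0 for 90.2% of the genes at least 2-fold higher in sphere-treated embryos, against 39.9% of all genes. It was below 0 for 325 of the 361 genes at least 2-fold lower, against 60.1% of all genes. The developmental change was fitted as a straight line across all genes, from means that include the same shield groups. Its removal also takes out any onset effect that follows that change, and it moves lists with a steep change most. The medians that remain are therefore not onset effects free of developmental time. The medians of the endoderm, notochord and FGF lists stood at -0.74, -0.99 and -0.59 once the fitted developmental change was taken out. That of the germ cell and maternal list went from -0.56 to -0.26, that of the p53 and stress list from -0.33 to -0.20 and that of the ribosomal protein list from 0.27 to 0.06. The Nodal signalling median went from -0.23 to -0.16. In 7 of the 27 lists the sign of the median changed. The pseudocount also moved several shield medians, among them that of forebrain, to 0.96 with 1 and 0.13 with 20. Removal of the developmental change took the median from 0.41 to -0.23 for forebrain, 0.29 to -0.33 for midbrain and hindbrain, 0.26 to -0.13 for posterior and 0.22 to -0.27 for neurogenesis genes. It went from 0.11 to -0.08 for extracellular matrix, 0.11 to -0.09 for retinoic acid and -0.10 to 0.02 for neural crest genes. The epidermis median went from 0.43 to 0.34, the yolk syncytial layer median from 0.47 to 0.04 and the heart median from -0.37 to -1.41.

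By size, 315 genes were at least 2-fold higher and 361 at least 2-fold lower in sphere-treated shield embryos. The limma-moderated test was passed by 312 and 353 of these, and it called 2894 genes higher and 2825 lower at any size. Which direction held the majority depended on scaling, with 2781 and 2937 called with TMM factors and 2457 and 3244 with equal totals. Without moderation of the variance the calls were 861 and 574, and with the fitted developmental change removed 170 and 128 genes stood at least 2-fold apart. The authors' deposited table calls 776 records higher and 1139 lower at this stage.

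**Figure D1:**
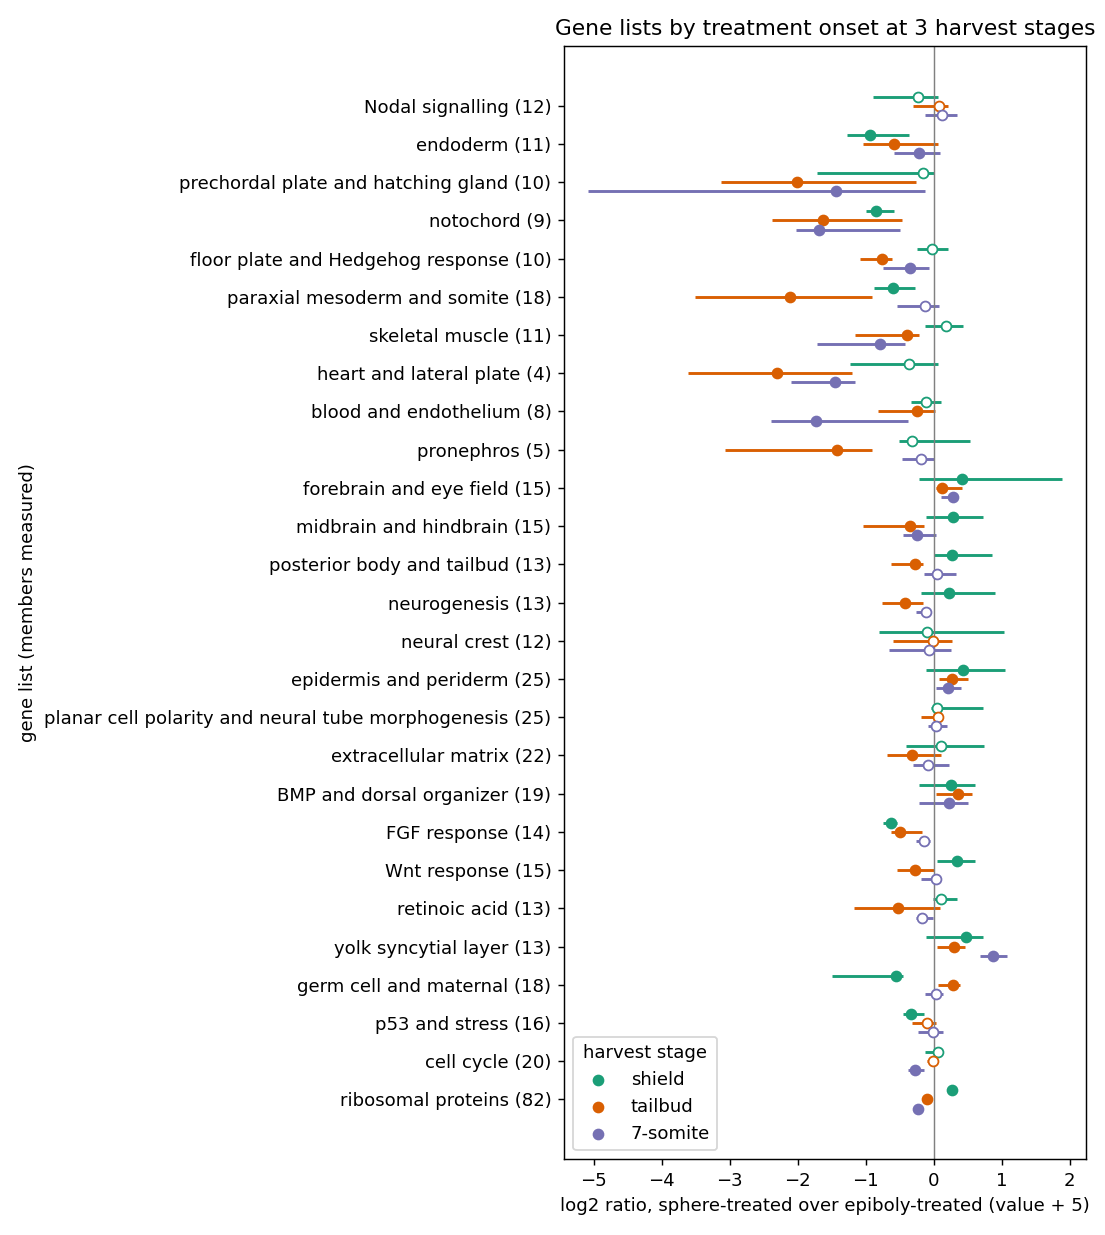
Median log2 ratio of sphere-treated over epiboly-treated embryos (horizontal axis, from values + 5) for 27 gene lists (vertical axis, with the members measured) at shield (green), tailbud (orange) and 7-somite (purple). Bars span the quartiles of the members, and filled points lie outside the central 95% of 10000 matched random lists. The paraxial mesoderm median is at -0.60, -2.11 and -0.13 over the 3 stages.

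The second comparison asked the same question at tailbud, at the end of gastrulation. The 5 named genes that fell most in sphere-treated embryos included regulators of mesoderm and endoderm. tbx1 went from 370 ± 44 to 2 ± 0.577 (log2 ratio -5.74, limma adjusted p = 3.0e-06). The cathepsin gene ctslb.4 went from 1467 ± 175 to 28 ± 3.84 (log2 ratio -5.48), and fsta, which encodes follistatin, from 1871 ± 163 to 47 ± 11.4 (log2 ratio -5.17). twist1a, of mesoderm and neural crest, went from 534 ± 58.5 to 10 ± 2.33, and foxa2, of endoderm and axial mesoderm, from 402 ± 47.6 to 7 ± 2.19 (log2 ratio -5.08, limma adjusted p = 1.2e-05).

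Paraxial mesoderm showed 13 of 18 genes lower and 0 higher (15 and 0 adjusted over the list alone), 12 of the 13 at least 2-fold, and a median of -2.11. Tested directly, the ratio was lower at tailbud than at shield for 10 of the 18. ripply1 fell from 509 ± 37.2 to 20 ± 0.882, and tbx6, a gene of the presomitic mesoderm, from 1731 ± 148 to 98 ± 50.5. The somite genes fell likewise, meox1 from 466 ± 21.9 to 26 ± 10.3, and foxc1a from 1289 ± 110 to 99 ± 44. In the prechordal plate and hatching gland list 6 of 10 genes fell and 1 rose (6 and 1 adjusted over the list alone), ctslb from 240 ± 33.7 to 3 ± 0.333. Notochord genes fell in 4 of 9 cases (7 adjusted over the list alone), with emilin3a at 203 ± 18.1 and 11 ± 3.18. sox17 fell from 246 ± 51.5 to 7 ± 1.2, but the endoderm list was mixed, with 3 of 11 genes lower and 2 higher (6 and 2 adjusted over the list alone). In the heart and lateral plate list, 3 of 4 measured genes fell (3 adjusted over the list alone). In the pronephros list 3 of 5 fell (3 adjusted over the list alone), and the intermediate mesoderm gene osr1 went from 582 ± 49.2 to 25 ± 2.33. In the skeletal muscle list 4 of 11 fell (5 adjusted over the list alone), and myod1, which specifies muscle, went from 112 ± 16.8 to 8 ± 3.38. Of 8 blood and endothelium genes 1 fell and 1 rose (2 and 1 adjusted over the list alone).

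Of 13 retinoic acid genes 6 fell and 0 rose (6 and 2 adjusted over the list alone). The gene of the enzyme that makes retinoic acid, aldh1a2, fell from 1209 ± 119 to 83 ± 22.4. The gene of the step before it, rdh10a, fell from 2085 ± 234 to 117 ± 43.8, and dhrs3a from 209 ± 7 to 16 ± 2.73. The hindbrain genes meis3 (2425 ± 58.8 to 772 ± 107) and hoxb1a (211 ± 10.3 to 29 ± 8.74) were among the 4 of 15 midbrain and hindbrain genes that fell (4 adjusted over the list alone), and 0 rose. Floor plate and Hedgehog response genes fell in 5 of 10 cases (9 adjusted over the list alone), and 0 rose. Of 14 FGF response genes 4 fell and 1 rose (9 and 1 adjusted over the list alone), and of 15 Wnt response genes 4 fell and 2 rose (9 and 3 adjusted over the list alone). Of the 19 BMP and dorsal organizer genes 5 rose and 3 fell (9 and 3 adjusted over the list alone). The list median was 0.35 but the list mean -0.18, and the BMP antagonist gene nog1 and admp, which encodes a BMP-family ligand of the organizer, fell by 2.54 and 1.85 on the log2 scale.

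Few genes were higher. szl rose from 2392 ± 245 to 5378 ± 280 (log2 ratio 1.17, limma adjusted p = 0.00093), and in the epidermis and periderm list 8 of 25 genes rose and 0 fell (10 and 0 adjusted over the list alone), dlx3b from 3399 ± 141 to 5706 ± 296, and tp63 from 2986 to 5007 (limma adjusted p = 0.0032). Of 15 forebrain genes 3 rose (5 adjusted over the list alone) and 0 fell, with hesx1 at 371 ± 22.2 and 753 ± 98.5. Of the 5 named genes that stood highest by ratio, after 1 record without a symbol had been passed over, 4 rose. These were pla2g4cl1 (42 ± 17.7 to 168 ± 17.2), the glycolysis gene gapdhs (203 ± 33.5 to 664 ± 228, limma adjusted p = 0.0498), egln3, a prolyl hydroxylase gene of the oxygen response (46 ± 3.51 to 156 ± 20), and syn1 (109 ± 7.84 to 336 ± 22.9). pde9ab did not pass the test (37 ± 15.5 to 112 ± 55.2, limma adjusted p = 0.28). The gapdhs call was lost with a pseudocount of 20 and with groups rescaled to equal totals.

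At tailbud 30 genes were at least 2-fold higher and 227 at least 2-fold lower in sphere-treated embryos. The limma-moderated test was passed by 15 and 179 of them, and it called 98 higher and 305 lower at any size. With the spread pooled over all 6 groups the calls were 316 and 623, and without moderation 3 and 39. The authors' deposited table calls 57 records higher and 160 lower.

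The third comparison took the 7-somite stage, when the neural plate is folding. Among the named genes, those of the hatching gland fell most. ctslb.4 was at 6808 ± 637 in epiboly-treated and 8 ± 4.49 in sphere-treated embryos (log2 ratio -9.03, limma adjusted p = 1.4e-07), and ctslb at 1071 ± 96.4 and 1 ± 1. The hatching enzyme gene he1.2 stood at 1073 ± 123 and 8 ± 2.03, and he1.1 at 749 ± 82.3 and 7 ± 0.667. Together with MGC174155 (287 ± 18.6 and 1 ± 0.667) these are the 5 most lowered named genes, after 5 with clone names had been passed over. Of the 10 genes of the prechordal plate and hatching gland list 6 fell and 0 rose (6 and 0 adjusted over the list alone).

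Notochord genes fell in 7 of 9 cases (7 adjusted over the list alone), emilin3a from 1385 ± 229 to 133 ± 54.9 (log2 ratio -3.33, limma adjusted p = 0.00072) and col8a1a from 330 ± 47.5 to 99 ± 10.5. The collagen gene col2a1a fell from 886 ± 146 to 158 ± 20.8. Blood and endothelium genes fell in 5 of 8 cases with 1 rising (6 and 2 adjusted over the list alone). The regulator of blood formation tal1 went from 610 ± 47.8 to 80 ± 26.9, etsrp, which specifies endothelium, from 675 ± 43.4 to 106 ± 42.4, and fli1 from 400 ± 21.5 to 76 ± 20.3. In the skeletal muscle list 8 of 11 genes fell and 0 rose (8 and 0 adjusted over the list alone), with the slow myosin gene smyhc1 at 522 ± 105 and 67 ± 24.9. All 4 measured heart and lateral plate genes fell (4 adjusted over the list alone), hand2 from 453 ± 16.7 to 157 ± 14.3 and tbx1 from 261 ± 16 to 13 ± 1. Of 10 floor plate and Hedgehog response genes 6 fell (6 adjusted over the list alone), foxj1a, which drives motile cilia, from 286 ± 24.1 to 99 ± 20.1. Of 11 endoderm genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), with foxa2 at 195 ± 19.2 and 45 ± 21.2.

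Paraxial mesoderm genes were close to equal at this stage. Of 18 genes 4 fell and 2 rose (4 and 2 adjusted over the list alone), with a median of -0.13 at percentile 8.95. tbx6 was at 2728 ± 197 and 2373 ± 534 (log2 ratio -0.20, limma adjusted p = 0.55) and meox1 at 1615 ± 123 and 1011 ± 281 (log2 ratio -0.67, limma adjusted p = 0.094), while ripply1 fell from 775 ± 42 to 375 ± 109. Tested directly, the ratio was higher at 7-somite than at tailbud for 13 of the 18 genes and lower for 0. In the pronephros list 1 of 5 genes fell (2 adjusted over the list alone). In the retinoic acid list 1 of 13 fell and 3 rose (2 and 3 adjusted over the list alone), and in the FGF response list 3 of 14 fell (3 adjusted over the list alone).

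**Figure D2:**
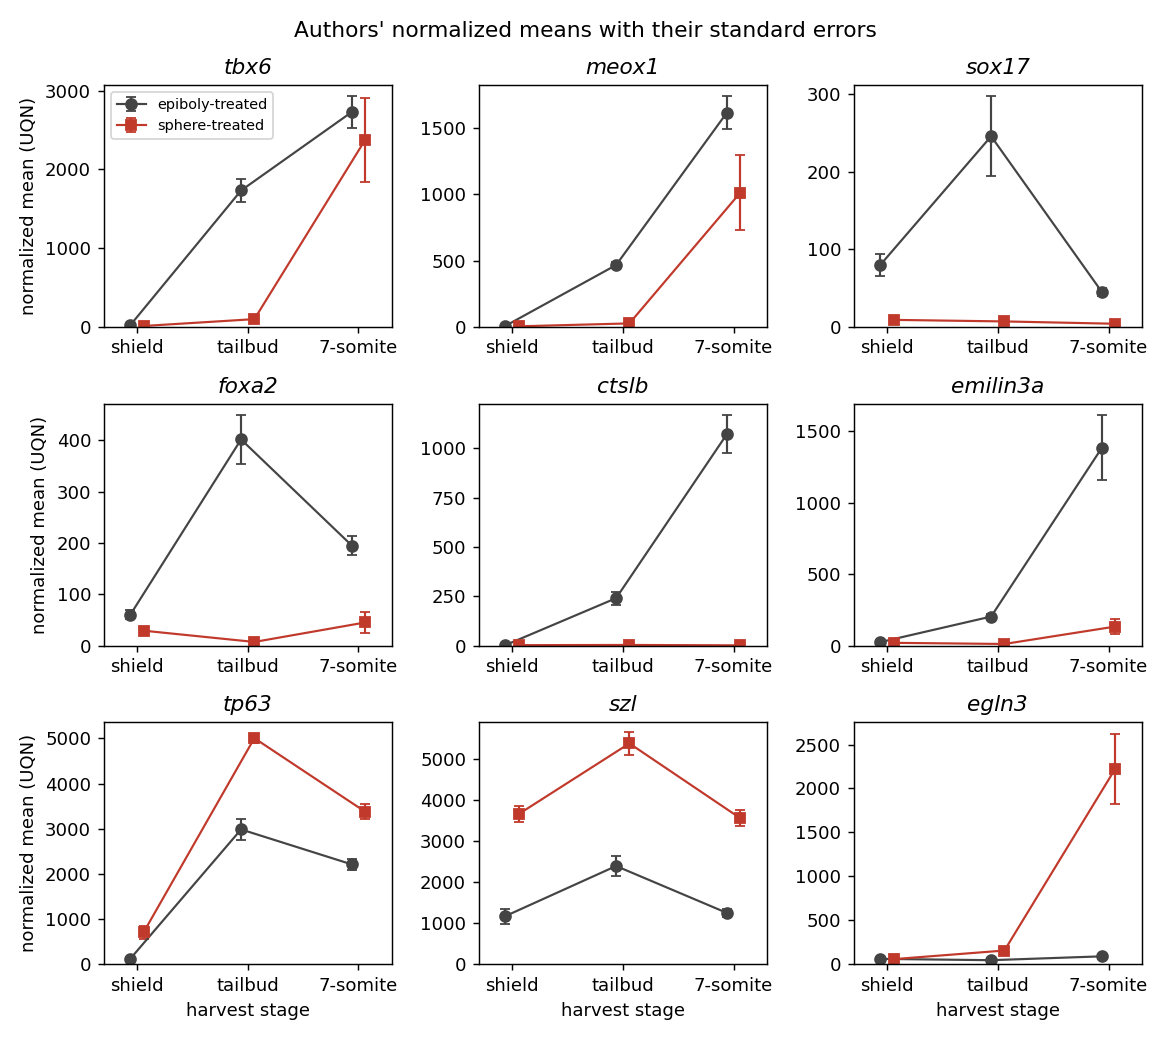
The authors' normalized means (vertical axis, UQN scale from 0) with their standard errors (bars) for 9 genes at the 3 harvest stages (horizontal axis), in epiboly-treated (grey circles) and sphere-treated (red squares) embryos. tbx6 went from 98 to 2373 between tailbud and 7-somite in sphere-treated embryos, whereas ctslb stayed at 3 and 1.

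Among genes higher at 7-somite, egln3 rose from 90 ± 30.6 to 2223 ± 400 (log2 ratio 4.55, limma adjusted p = 4.2e-05). It was followed by pfkfb3, which encodes a regulator of glycolysis (142 ± 13.1 to 1277 ± 250, log2 ratio 3.12). Next came the aldolase gene aldocb (97 ± 15.4 to 629 ± 74), cyp1b1 (21 ± 3.46 to 151 ± 12.8) and rpgra (14 ± 3.18 to 107 ± 11.7). On a list of low-oxygen response genes drawn up after these were seen, which leaves egln3, pfkfb3 and aldocb out, 23 of 34 measured genes rose and 1 fell (24 and 1 adjusted over the list alone). Genes of the yolk syncytial layer, the nutrient-exporting layer between yolk and embryo, rose in 9 of 13 cases and fell in 0 (11 and 0 adjusted over the list alone), with a median of 0.87. The lipoprotein genes apoa1b and mttp went from 12716 ± 1382 to 22864 ± 5149 and from 184 ± 23.7 to 655 ± 314. In the epidermis and periderm list 8 of 25 genes rose, or 13 with equal totals, and 0 fell (14 and 0 adjusted over the list alone), tp63 from 2211 ± 128 to 3378 ± 171. Of 15 forebrain genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), fezf2 from 513 ± 18.6 to 728 ± 71.3. Of the 19 BMP genes 9 rose and 3 fell (9 and 4 adjusted over the list alone), szl from 1250 ± 94 to 3558 ± 194.

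At 7-somite 144 genes were at least 2-fold higher and 110 at least 2-fold lower, and 129 and 110 of these passed the limma-moderated test. At any size the test called 1256 higher and 1796 lower. This split depended on scaling, and with groups rescaled to equal totals the counts were 1774 and 1179. Without moderation of the variance 245 and 452 were called. The authors' deposited table calls 40 records higher and 140 lower. Its rule differs from the rules used here, as it left 983 records at 1.5-fold or more uncalled at this stage.

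A list of genes linked to closure of the neural tube by planar cell polarity and cell shape was also compared. Of 25 measured, 11 rose and 3 fell at shield (11 and 3 adjusted over the list alone), 0 rose and 3 fell at tailbud (0 and 4). At 7-somite 3 rose and 2 fell (3 and 2), but 5 rose with TMM factors and 7 with equal totals. At the deposited scaling 0 changed by 2-fold past the test at any stage. List medians were 0.05, 0.07 and 0.03, at percentiles 58.6, 95.2 and 92.8, and list means were 0.24, -0.10 and 0.02. The upper quartile at shield was 0.73. The list entries wnt11 and wnt11r both matched the record now named wnt11, for which wnt11r is an older name. Any other gene formerly named wnt11 was not compared here. The matched record fell at 7-somite from 974 ± 63.6 to 551 ± 44.8 (log2 ratio -0.82, limma adjusted p = 0.0018), and wnt4 from 174 ± 14.1 to 107 ± 2.03. The kinase gene rock2b rose at shield from 673 ± 10.5 to 1146 ± 132 and at 7-somite from 1203 ± 23.1 to 1691 ± 152. The cadherin gene celsr2 rose at shield from 1885 ± 67.3 to 3718 ± 282 and was at 4663 ± 61 and 5327 ± 120 at tailbud (limma adjusted p = 0.16).

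The next comparison asked which differences were shared by the stages. tbx1, lhx1a, elapor1, foxa and fzd8b are 5 of the 7 genes that were at least 2-fold lower in sphere-treated embryos at all 3 stages, each past the limma-moderated test at each stage. The 1 gene at least 2-fold higher at all 3 was szl. elapor1 stood at 134 and 37 at shield, 125 and 9 at tailbud, and 62 and 9 at 7-somite. The forkhead gene foxa stood at 722 and 187, 132 and 40, and 141 and 21, in epiboly-treated and sphere-treated embryos. Tailbud and 7-somite shared 56 genes at least 2-fold lower, where 1.9 would be shared by independent lists of those lengths, and 8 higher, against 0.3. Shield and tailbud shared 25 lower (6.2 by chance) and 5 higher (0.7), and shield and 7-somite 9 lower (3.0) and 12 higher (3.4).

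Of the 27 lists 15 had a median outside the central 95% of random lists at shield, 22 at tailbud and 14 at 7-somite. Random lists would give 1.35, but members of a real list can vary together, so this contrast is not a test. At tailbud the 22 include the ribosomal protein (median -0.10), germ cell, yolk syncytial layer and neurogenesis lists, in which 0 genes passed the test per stage. Across genes, which are not independent replicates, the log2 ratios at tailbud and 7-somite correlated at Pearson's r = 0.48, those at shield and tailbud at r = 0.11, and those at shield and 7-somite at r = 0.10. Spearman's rho for these pairs was lower, at 0.32, 0.04 and 0.04. No control group is shared by these comparisons. When stages served as pairs, limma with harvest stage as a block called 0 genes higher and 0 lower, with 1002 genes at an unadjusted p under 0.05. Without the tailbud stage it called 120 higher and 40 lower, and without the shield stage 0 and 4. Adjusted over the list alone, the blocked test called genes in 15 of the 27 lists. Of 19 BMP and dorsal organizer genes it called 8 higher and 2 lower. It called 7 of 9 notochord, 7 of 10 prechordal plate and hatching gland, 6 of 14 FGF response, 4 of 11 endoderm and 4 of 10 floor plate genes lower, and 4 of 13 yolk syncytial layer genes higher. In 12 lists it called 0, among them the Nodal, paraxial mesoderm, skeletal muscle and planar cell polarity lists, and in the other 8 lists from 1 to 4.

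The last comparison followed development over both onsets. The 5 named genes that rose most from shield to tailbud included neural and posterior patterning genes. The eye field gene rx3 went from a mean of 1.5 over the 2 onsets to 1447.5 (log2 change 7.81, limma adjusted p = 4.3e-05), followed by nr2f5 (6 to 1977.5), hoxb9a (0.5 to 862), six3b (13.5 to 1837.5) and pax2a (5.5 to 883.5). The heart and lateral plate list had the highest median change of the 27 lists, 3.93, with 3 of 4 genes rising. In the forebrain list 13 of 15 genes rose, in the midbrain and hindbrain list 14 of 15, and in the posterior list 10 of 13 with 2 falling. The 18 germ cell and maternal genes all fell. mctp2b (872 to 5), lrmp (830.5 to 5.5), gcnt7 (682.5 to 8), fam169ab (2317.5 to 45.5) and the embryonic cyclin gene ccna1 (1321.5 to 21.5) fell most.

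From tailbud to 7-somite the genes that rose most were lamb2l (8.5 to 432.5), the eye and midbrain gene mab21l2 (20 to 786.5), sox10, a regulator of neural crest (15 to 584), en2b, of the midbrain-hindbrain boundary (7.5 to 355.5), and gfap, of radial glia (12 to 419.5). Those that fell most were nnr (452.5 to 25.5), the endoderm gene sox32 (335.5 to 19.5), slc2a12 (733.5 to 71.5), vrtn (1809 to 204.5) and add3b (1063.5 to 123.5). Of 11 skeletal muscle genes 6 rose and 0 fell, and of 22 extracellular matrix genes 12 rose and 0 fell.

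The limma fit called 2568 genes higher and 4791 lower at tailbud than at shield, and 1035 higher and 930 lower at 7-somite than at tailbud. With the deposited scaling the median gene changed by -0.21 on the log2 scale over the first step and by 0.02 with TMM factors. The counts were then 3560 and 3445, and with equal totals 3928 and 3059. Without the epiboly-treated tailbud mean, at the deposited scaling, they were 1407 and 2941. Relative to the median gene, list medians changed by 4.13 for heart and lateral plate, 3.19 for forebrain, 3.03 for midbrain and hindbrain and -2.24 for germ cell and maternal genes. The second step gave 1201 and 650 with equal totals. It depended on single groups: without the sphere-treated 7-somite mean the counts were 119 and 177, and without the epiboly-treated shield mean 2232 and 2049.

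**Figure D3:**
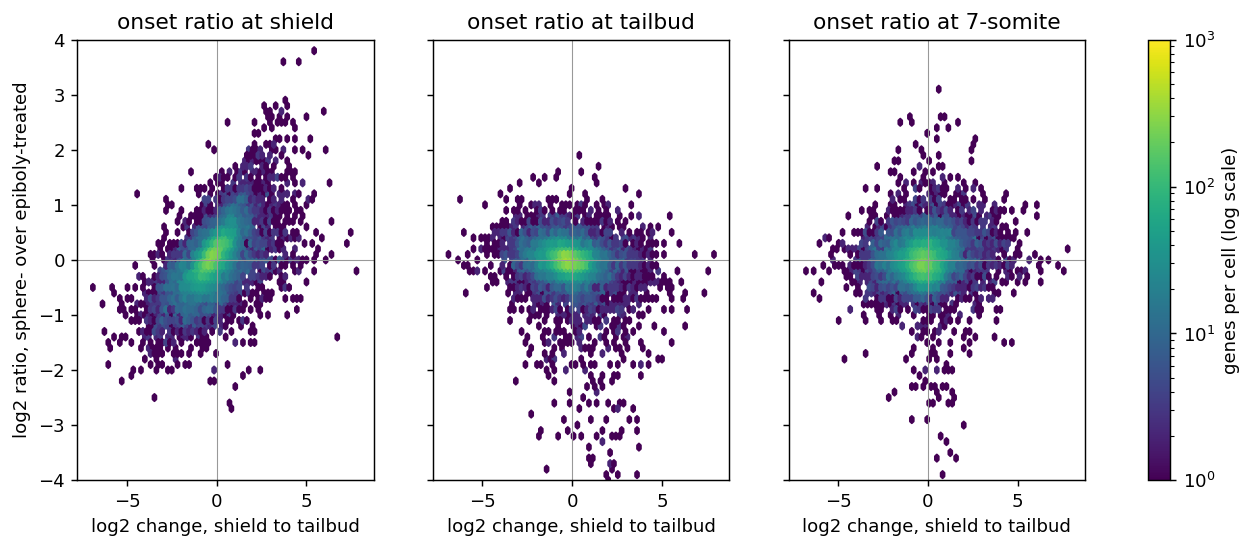
Number of genes (color, log scale) by log2 change from shield to tailbud over both onsets (horizontal axis) and log2 ratio of sphere-treated over epiboly-treated embryos (vertical axis) at shield, tailbud and 7-somite. Pearson's r across genes at shield is 0.58, where both axes use the shield means, and 0.03 at 7-somite. Not drawn are 15 genes at tailbud and 14 at 7-somite beyond a log2 ratio of 4 in size.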

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

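The tests per stage, and those of the difference between stages, were chosen only after the standard errors had been seen. In the weighing below, the tests of a shared effect at shield and tailbud, of mixed times behind 1 shield mean, of other rising genes at tailbud and of the yolk layer against the epidermis were also chosen only after the result was seen.

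The onset difference itself differed between harvest stages, by a test of the difference. Between shield and tailbud it differed for 3050 genes, 74 of them among the 143 named. Between shield and 7-somite it differed for 5046 genes, 80 of them named, and between tailbud and 7-somite for 447, 41 of them named. Opposite changes of at least 2-fold, with the difference past the test, were found for 9 genes between shield and tailbud. The clock gene per1b (log2 ratio -1.88 at shield and 1.43 at tailbud, where its limma adjusted p was 0.0753) and hoxb1b (1.86 and -1.31) are examples chosen after their values were seen. Between shield and 7-somite there were 7 such genes, among them insig1 (-1.45 and 1.36), also chosen after its values were seen, and between tailbud and 7-somite 1 record without a symbol.

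The first pattern is the wide set of onset differences at shield. An earlier start of inhibition could act on the same genes at shield as later. Against this as the whole cause, the shield and tailbud ratios correlated across genes at r = 0.11. This r over all genes does not weigh against a shared effect on part of them. Of genes at least 2-fold changed, 25 were lower at both stages (6.2 by chance) and 5 higher (0.7). Another 6 went from higher to lower (5.4 by chance) and 3 from lower to higher (0.8). A candidate explanation is that the sphere-treated shield embryos were collected at a later developmental time, as the shield ratio followed the change from shield to tailbud (r = 0.58). The 3 values behind the sphere-treated mean may also come from embryos of different times. Their relative spread rose with the size of that change (Spearman's rho 0.354, and 0.118 in the epiboly-treated group). This rho was not adjusted for expression level, and the onset ratio follows the same change, so mixed times are not shown. An effect of inhibition limited to shield stage, or on the pace of development, stays open and untested. The endoderm, notochord and FGF list medians were -0.74, -0.99 and -0.59 after the fitted developmental change was taken out. In 7 of 27 lists the sign changed. The fit also removes any onset effect that follows the same change, so these medians cannot part the causes.

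The second pattern is the fall of paraxial mesoderm genes at tailbud, where 13 of 18 fell and 0 rose, against 4 and 2 at 7-somite. A scaling offset shared by all genes is argued against, as the median gene had a log2 ratio of -0.0088 at tailbud and the list median was -2.11. Centring on the median gene, which left it at -2.10, could move it little and adds nothing to this. For a younger sphere-treated tailbud group as the whole cause, 544 other genes that rose at least 4-fold from shield to tailbud were examined. Their median ratio was -0.17 (quartiles -0.61 and 0.13), and that of the 5 list members past the same cut was -2.15. The rise was averaged over both onsets, so genes held back in the sphere-treated tailbud group missed the cut more easily. The median of the 544 therefore cannot exclude that cause. A younger group, as the whole or part of the cause, cannot be told apart from an effect of the onset. The correlation with the change from shield to 7-somite, r = -0.328, lies between the bounds set for either reading. The biological explanation that the design gives, an effect of the earlier onset on paraxial mesoderm that is smaller at 7-somite, stays open and was not tested.

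The third pattern is the rise of yolk syncytial layer genes at 7-somite, with a list median of 0.87. The median was also high at shield (0.47, percentile 99.99) and at tailbud (0.30, percentile 100), where 0 genes passed the test per stage. Tested directly, the ratio differed between tailbud and 7-somite for 0 of 13 genes, and was higher at 7-somite than at shield for 4. The rise is therefore not shown to be particular to 7-somite. An older sphere-treated group cannot be told apart from an effect of the onset, since no later stage was measured and such a group need not follow the earlier change from shield to tailbud (r = 0.0296 with the 7-somite ratio). A smaller share of embryo cells in the sphere-treated sample cannot be told apart from it either. At 7-somite the yolk layer median exceeded that of the epidermis list by 0.67 (95% resampling interval 0.40 to 0.92). The epidermis is itself embryo tissue, however, so a smaller share also predicts this difference. The bounds written for both tests were wrong for these reasons, and the effect of the onset was not tested.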

How the results depend on the processing

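Alternatives chosen only after the data were seen are the removal of the fitted developmental change and every alternative of the test per stage.

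Counts by size moved with the threshold, by construction. At 1.5-fold they were 949 higher and 1179 lower at shield, 204 and 499 at tailbud and 605 and 346 at 7-somite. At 3-fold they were 98 and 48, 3 and 115, and 30 and 59. With the higher mean at least 200 they were 186 and 224 at shield, 9 and 118 at tailbud and 66 lower at 7-somite. A pseudocount of 20 left 17 higher at tailbud, and removal of the fitted developmental change left 170 and 128 at shield. A pseudocount of 1, a level of 20 and the scaling alternatives kept the size counts within 1.5 times.

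Without moderation the test per stage called 861 higher and 574 lower at shield, 3 and 39 at tailbud and 245 and 452 at 7-somite, where the degrees of freedom are fewer by construction. With the spread pooled over 6 groups it called 316 and 623 at tailbud. Scaling turned the majority at shield, with 2457 higher and 3244 lower with equal totals. Equal totals gave 1179 lower at 7-somite, where the median ratio moves from -0.02 to 0.04.

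The step from shield to tailbud gave 3928 higher and 3059 lower with equal totals, so the direction of the majority depends on scaling. Leaving out 1 group mean at a time gave 1407 to 3156 higher and 2941 to 4802 lower, with the lowest counts without the epiboly-treated tailbud mean. From tailbud to 7-somite the ranges were 119 to 2232 higher and 177 to 2049 lower. The counts were 2232 and 2049 without the epiboly-treated shield mean, 2222 and 2043 without the sphere-treated one, 627 and 470 without sphere-treated tailbud, 383 and 374 without epiboly-treated 7-somite, and 119 and 177 without sphere-treated 7-somite. The stage-blocked onset test gave 0 to 120 higher and 0 to 40 lower when 1 stage was left out, with 120 and 40 without tailbud and 0 and 4 without shield. The cause was not tested.

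Correlations of the onset ratios kept their sign. Between shield and tailbud r was 0.114 with a mean of at least 50, and Spearman's rho 0.0407. Between shield and 7-somite r was 0.107 with a pseudocount of 1 and 0.0818 with 20, and rho 0.0411. Between tailbud and 7-somite these were 0.505, 0.448 and 0.320. The cause was not tested.

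The BMP list at tailbud reversed from a median of 0.35 to a mean of -0.18, which large falls of fsta, nog1 and admp produce. Lists outside the central 95% of random lists numbered 11 to 16 of 27 at shield, 20 to 22 at tailbud and 13 to 15 at 7-somite over the alternatives. With a pseudocount of 1 the shield medians moved to 0.96 for forebrain, 0.58 for midbrain and hindbrain and -0.57 for heart, and the tailbud median to -2.24 for prechordal plate. With 20 they moved at shield to 0.13 for forebrain, -0.16 for heart, -0.71 for endoderm and -0.61 for notochord, at tailbud to -1.55 for prechordal plate, -0.88 for notochord and -1.65 for paraxial mesoderm, and at 7-somite to -1.04 for prechordal plate. In 7 further cases the list mean lay beyond the spread of the median. Calls within lists moved by over 1.5 times under a scaling at 7-somite for higher genes of the planar cell polarity (3 to 7), epidermis (8 to 13), Wnt (1 to 3), blood (1 to 2), cell cycle and p53 lists (0 to 1), and for lower genes of the ribosomal (63 to 25), extracellular matrix (5 to 3) and posterior lists (2 to 1). Lower posterior genes went from 1 to 2 at shield and from 2 to 1 at tailbud.

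Of 429 values of named genes none reversed under the 5 alternatives. Calls were lost for 1 value with a pseudocount of 20, 5 with equal totals and 42 with the pooled spread, and gained for 3, 7 and 22.

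A quasi-likelihood test on whole reads was not run, as rounded means hold no whole reads. Replicates could not be left out. The filter at a mean of 10 removed 0 genes, so its absence says nothing about stability. Depth is unknown, and the table's minimum level limits what can be said of low genes.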

Other observations

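The low-oxygen list and its test were chosen only after egln3, pfkfb3, aldocb, gapdhs and slc16a3b had been seen, but before the values of its members.

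Cell cycle genes were split at shield, where 6 of 20 rose and 5 fell (6 and 5 adjusted over the list alone). At tailbud 0 passed, and at 7-somite 14 fell and 0 rose (15 and 0 adjusted over the list alone), with mcm2 at 9506 ± 210 and 6923 ± 174. With equal totals 10 fell and 1 rose. Of 82 ribosomal protein genes 55 rose at shield (66 adjusted over the list alone), with a median of 0.27, and 39 with equal totals. That median was 0.06 after the fitted developmental change was taken out. At tailbud 0 passed, and at 7-somite 63 fell (78 adjusted over the list alone), with a median of -0.24, but 51 with TMM factors and 25 with equal totals. Of 16 genes of the p53 and stress list 9 fell and 1 rose at shield (10 and 2 adjusted over the list alone), 0 passed at tailbud, and 1 fell at 7-somite (1 adjusted over the list alone).

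In the neural crest list 4 of 12 genes rose and 5 fell at shield (4 and 6 adjusted over the list alone), 1 rose and 2 fell at tailbud (2 and 3), and 4 rose and 6 fell at 7-somite (4 and 6). snai1b fell at tailbud from 525 ± 50.5 to 127 ± 7.31, and sox10 at 7-somite from 720 ± 77.4 to 448 ± 28.2. In the neurogenesis list 4 of 13 rose and 2 fell at shield (4 and 2 adjusted over the list alone), 0 passed at tailbud (1 and 2), and 2 fell at 7-somite (0 and 2). Of 22 extracellular matrix genes 8 rose and 4 fell at shield (8 and 4 adjusted over the list alone), 3 fell at tailbud (1 and 6), and 6 rose and 5 fell at 7-somite (6 and 6). has2 went from 222 ± 29 to 46 ± 1.33 at tailbud.

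Other lists had few calls at the stages not given above, with the counts adjusted over the list alone in parentheses. At shield 5 midbrain and hindbrain genes rose (5), 5 retinoic acid genes rose and 1 fell (5 and 1), 4 skeletal muscle genes rose (4) and 2 blood genes rose (2). Also at shield 2 heart genes fell (2), 1 pronephros gene rose and 2 fell (1 and 2), and 1 floor plate gene rose and 2 fell (1 and 2). At tailbud 1 posterior gene rose and 2 fell (2 and 6), and 0 passed in the Nodal (2 and 1), yolk syncytial layer (3 and 0) and germ cell lists (0 and 0). At 7-somite 2 Nodal genes rose and 1 fell (2 and 1). Also at 7-somite 1 midbrain and hindbrain gene rose and 4 fell (1 and 6), 3 posterior genes rose and 2 fell (3 and 2), 1 Wnt gene rose and 2 fell (1 and 2), and 1 germ cell gene rose (0).

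The median and the mean of a list differed in sign for Nodal signalling at tailbud (0.08 and -0.15), blood and endothelium at shield (-0.12 and 0.01), neural crest at shield (-0.10 and 0.08), Wnt response at 7-somite (0.03 and -0.08), cell cycle at shield (0.06 and -0.02), and, at tailbud, planar cell polarity (0.07 and -0.10) and BMP and dorsal organizer (0.35 and -0.18). With TMM factors the sign of the median changed for cell cycle and neural crest at tailbud and for p53 and stress at 7-somite.

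Genes called by the authors' deposited table also passed the test per stage in 1848 of 1912 cases at shield, 130 of 217 at tailbud and 164 of 180 at 7-somite. In the other direction, 78, 156 and 176 genes at least 2-fold changed at these stages were not called by the authors.

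A hypothesis for egln3, pfkfb3, aldocb and gapdhs at 7-somite is a wider response to low oxygen in the sphere-treated group. Of 49 genes listed for that response 34 were measured, and their median ratio at 7-somite was 0.74, at percentile 100 of matched random lists, with 23 higher and 1 lower. At shield the median was -0.02 at percentile 31.5, with 9 higher and 9 lower. At tailbud it was 0.14, also at percentile 100, but with 1 higher, 1 lower and 32 not past the test. Examples chosen after their values were seen are p4ha1b (1164 to 4806), pgk1 (173 to 817) and ldha (148 to 610), while pfkfb4b fell from 1740 to 1209. Such a response may come from crowding or handling of 1 group as well as from the earlier inhibition, and no label used here tells these apart.

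The stage-blocked onset test called 0 genes, with 1002 at an unadjusted p under 0.05, and the 6 means have 10 splits into 3 and 3. As the real split called 0, each of the 10 gives at least as many by construction, and the comparison decides nothing. The highest of the other splits gave 32 genes, in 2 splits that do not part the stage pairs. The splits are also too few for a share under 0.05.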
